A study of Mus musculus with 72 samples.

How the data were processed

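The series holds 72 mouse liver samples on single-colour Affymetrix arrays: 2 cohorts, 2 genotypes, 6 time points and 3 replicates per group. Groups, times and replicate numbers were taken from the sample titles. Per the submitters' processing notes, the arrays were processed with Affymetrix Expression Console 1.1.1 and PLIER 2.0; the normalization settings and the genome build are not given in the sources used here. The deposited value table holds probe set intensity on a linear scale, as its range shows, with a median of 43.9 to 53.8 per array. Each of its columns was matched to 1 sample by name, and 0 columns were left unmatched. The 99th percentiles of the 2 cohorts did not overlap, so that separate normalization stays possible. No coordinates are given, because the build is not stated; the gene table of the reference used here served for names and for gene order alone.

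Of 41345 probe sets, 23521 carried 1 gene symbol, 1814 several and 16010 none. Only those with 1 symbol were named. Entrez identifiers matched the reference table for 23328 of them, and 0 symbols differed. Where a gene had several probe sets (1082 of 22180 genes), the one with the highest mean over all 72 arrays was used. The other probe sets of a named gene differed in sign from it for Tef and, in the SIRT1 cohort, for Hspb1. Values were taken as log2(value + 16), and the lowest 40% of genes by mean over all arrays (under 6.00) were left out, so that 13308 genes were tested.

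Each cohort was fitted with limma 3.58.1 in R 4.3.3 as 12 group means over its 36 arrays, with empirical Bayes moderation and a trend with intensity. KO minus WT was tested averaged over the 6 times, and at each time with 1 Benjamini-Hochberg correction over all genes and times together. The threshold was an adjusted p of 0.05 in all tests. Rhythms were tested per set of 18 arrays with a moderated F of a 24 h cosine (2 coefficients), amplitude being the fitted peak minus trough. The difference in rhythm was tested by genotype times cosine terms over 36 arrays among genes rhythmic in either genotype, with a new correction over those genes. The amplitude ratio and the correlation between cohorts were tested by relabelling the arrays within time points, 100 times. The difference between the 2 effects was fitted over all 72 arrays with 24 group means, each KO against its own WT. Gene lists (35, fixed beforehand) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which tests whether a list's genes move on balance one way without comparing them with other genes. Correlations across samples used quantile-normalized values with group means removed, permuted over the 36 arrays 100000 times, two-sided. Removing 12 group means leaves the 36 values dependent within groups, which the permutation ignores, so its p-values are too small.

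Genes named in the text follow a rule fixed before the data were examined: Sirt6, Sirt1 and the core clock list; per cohort, the 8 highest and 8 lowest changes among genes past the threshold with 1 direction at all 6 times; up to 6 genes of lower and 6 of higher amplitude with a difference in rhythm; up to 4 members with the smallest p in each list past the threshold or with 3 or more members past it; the 6 genes of largest amplitude among those rhythmic in all 4 sets; and the 6 largest differences between the knockouts in each direction. Predicted genes were counted but not named. Asns, Cox10 and Krt33b were named outside this rule, after their values were seen.

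The steps were tested on simulated data with the real genes' means and spreads and known changes. The noise of each gene was drawn independently, without the correlation between genes of the real arrays. In the SIRT6 cohort 52.6% of the variance within groups lay on 1 component, so the shares below hold for uncorrelated noise alone. The averaged test recovered 61.2%, 94.0% and 98.5% of genes changed by 0.25, 0.5 and 1 (log2) in the SIRT6 cohort, and 74.6%, 100% and 100% in the SIRT1 cohort, among 13308 genes. The rhythm test recovered 54.5%, 84.3% and 97.0% of amplitudes of 0.5, 1 and 2 in the SIRT6 WT design and 59.0%, 99.3% and 100% in the SIRT1 WT design. The test of a difference in rhythm recovered 55.2%, 80.6% and 93.9% (346 genes tested, SIRT6 design) and 47.8%, 98.5% and 100% (372 genes, SIRT1 design). It made 20 false calls among 173 and 17 among 181, more than the nominal 5 per 100; the reason was not tested.

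The tests were also run with quantile normalization, centring of array medians, pseudocounts of 1 and 64, no filter and a filter of the lowest 60%, a block for the replicate number, array weights, no trend, all probe sets, 1 fit of all 72 arrays, a threshold of 0.01, an F test over the 6 times, a rank test of the JTK kind over 12 phases, other gene sets for the difference in rhythm, and with each array left out in turn. Added after the data were examined were the array's upper quartile and an acute phase score as covariates, and 1 array left out for its large residual spread (WT ZT12 replicate 1 of the SIRT6 cohort). The score is the mean of the acute phase list, which includes Hamp2.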

Results

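Gene expression was measured in mouse livers collected every 4 h over the day under a 12 h light and 12 h dark cycle, at zeitgeber times (ZT, hours after lights on) 0, 4, 8, 12, 16 and 20. A first cohort, whose strain label names a mixed background, held mice labelled wild type (WT) and mice labelled as liver knockouts (KO) of SIRT6, and a second, of strain C57BL/6, held mice labelled WT and mice labelled as liver KO of SIRT1. SIRT6 and SIRT1 are NAD-dependent deacylases of the sirtuin family, and the series asked how each contributes to the daily cycle of liver transcripts. The 24 groups of cohort, genotype and time held 3 samples each, for 72 arrays with 1 biotin-labelled RNA per array. The labels name replicates without saying that each came from another mouse, so the p-values measure the spread between these samples. The median probe set intensity of an array lay between 43.9 and 52.9 in the SIRT6 cohort and between 44.4 and 53.8 in the SIRT1 cohort, and the number of arrays limits the precision. The lowest correlation between replicate arrays was 0.904 in the SIRT6 cohort and 0.973 in the SIRT1 cohort. Within each cohort 0 pairs of arrays held identical values. All levels and changes are on the log2(intensity + 16) scale, which understates changes of weakly expressed genes. The 99th percentile of intensity ran from 3217 to 3430 in one cohort and from 3440 to 3641 in the other, a gap that leaves open whether the cohorts were normalized separately, so levels are compared within a cohort.

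The targeted genes were examined first, as a check of the labels. The probe set of Sirt6 (17243432) was higher, not lower, in the arrays labelled SIRT6 KO, at 7.89 ± 0.10 (SD, n = 18) against 7.32 ± 0.18 (n = 18) in the WT-labelled arrays, a log2 fold change of 0.57 ± 0.05 (SE) or 1.49-fold (limma adjusted p = 8.9e-09). All 18 KO-labelled arrays lay above every WT-labelled array, the lowest of them at 7.76 and the highest WT-labelled array at 7.60. In the SIRT1 cohort the Sirt6 probe set read 7.46 ± 0.14 and 7.44 ± 0.14, with the highest arrays at 7.70 (WT) and 7.62 (KO-labelled). A second probe set, listed for Sirt6 together with 4 predicted genes, read 9.34 ± 0.12 and 9.32 ± 0.11 in the SIRT6 cohort. The probe set of Sirt1 (17241582) read 8.74 ± 0.18 in WT and 8.74 ± 0.11 in KO-labelled arrays of the SIRT1 cohort (adjusted p = 0.96). Where these probes lie relative to the deleted exons is not given in the sources used here, and a probe set outside the deleted part checks nothing, so the loss of either gene is not shown by these arrays. A higher level of Sirt6 is not the fall that loss of its transcript would give, but with the probe position unknown it does not decide the label. The SIRT6 cohort is therefore described by its labels throughout, and the direction of every difference in it rests on those labels.

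**Figure D1:**
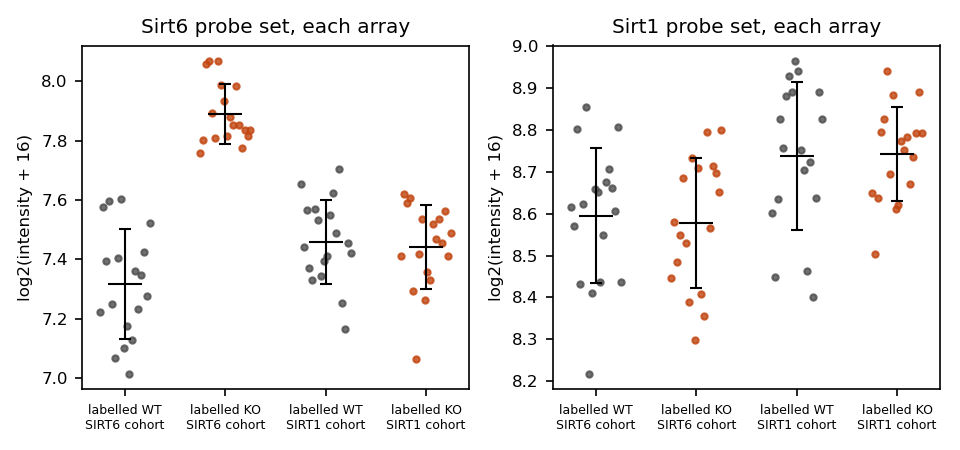
Level of the Sirt6 (left) and Sirt1 (right) probe sets in each of the 72 arrays, as log2(intensity + 16), by genotype label and cohort. Points are arrays, and the black marks are the mean and SD of 18 arrays; the KO-labelled arrays of the SIRT6 cohort lie between 7.76 and 8.07 for Sirt6, above all WT-labelled arrays of that cohort.

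Averaged over the day, livers labelled SIRT6 KO differed from their WT in 880 of 13308 genes, 451 of them higher and 429 lower, and most differences were small, with a median size of 0.21 on the log2 scale. Among genes with 1 direction at all 6 times, the largest increases were in Hamp2, a relative of the iron hormone hepcidin, at 2.87 ± 0.34 (SE) and 7.31-fold (adjusted p = 2.2e-06, above the WT mean of the same time in 17 of 18 KO-labelled arrays), in the sulfotransferase Sult2a7 at 2.69 ± 0.35 (adjusted p = 8.1e-06, 18 of 18), and in the cytochrome P450 Cyp2d12 at 2.51 ± 0.61 (adjusted p = 0.010, 18 of 18). Increases of 1.81 to 2.02 were found in Lrtm1, a leucine-rich repeat membrane protein, Serpina12, the serpin vaspin, Apba2, an adaptor that binds amyloid precursor protein, Ptgds, a prostaglandin D synthase, and Ly6f, a Ly6 family surface protein, with adjusted p from 1.2e-09 for Apba2 to 0.021 for Serpina12. Cyp2d12 ran from 5.0 to 11.38 in the WT arrays, 12 of 18 below a gap of 3.13, and from 9.05 to 11.50 in the KO-labelled arrays. Serpina12 ran from 4.35 to 10.71 in the WT and from 8.92 to 10.72 in the KO-labelled arrays. In both genes the highest WT arrays thus reached the KO levels. The largest decreases among such genes were in Olfm3, an olfactomedin, at −1.30 ± 0.12 (adjusted p = 2.9e-08, lower in all 18), in the C2 domain gene Tc2n at −1.29 ± 0.10 (adjusted p = 1.2e-09, 18 of 18), in the P450 pseudogene Cyp2c53-ps at −1.19 ± 0.34 (adjusted p = 0.034, 16 of 18), and in the membrane protein gene Tmem184c at −1.19 ± 0.17 (adjusted p = 3.3e-05, 18 of 18). The fatty acid transporter Cd36 changed by −0.91 ± 0.16 (adjusted p = 0.00064), Srgap3 by −0.84, the Src-like kinase Frk by −0.84, and Smad9 of the BMP pathway by −0.82. The balance of directions moved with the fit, to 689 higher and 1020 lower genes with the acute phase score as covariate. That score is the mean of a list that includes Hamp2. Its 28 measured genes had a mean change of 0.22 and a median of 0.05, so this fit does not adjust for inflammation alone. Only 67 of the higher and 20 of the lower genes differed by at least 1.5-fold. Of the 880, 374 higher and 306 lower genes kept 1 direction at all 6 time points. Probe sets of families with near-identical members, such as the Cyp2d, Cyp2c, Sult2a, Ly6 and Mup genes, may also read relatives. Leaving out 1 array ended the call of Cyp2c53-ps for 15 of the 36 arrays, of Smad9 for 9 and of Frk for 1.

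Camera at the preset correlation called 4 of the gene lists fixed beforehand. Relabelled arrays gave a median of 7 lists, and 79 of 100 relabellings reached 4, so the calls below are not set apart from chance. Among these lists, the cholesterol synthesis genes were lower on balance in the KO-labelled livers. Of 20 measured members 19 had a lower mean there (median −0.14, camera adjusted p = 0.0036, but adjusted p = 0.957 with an estimated correlation), yet 1 passed on its own, the sterol reductase Tm7sf2 at −0.22 ± 0.07 (adjusted p = 0.038), and 1 did when adjusted over the list alone. The sterol sensor partner Insig1 changed by −0.20 (adjusted p = 0.099) and Hsd17b7 by −0.26 (adjusted p = 0.12). The heat shock genes were lower by the same test (13 of 16 lower, median −0.10, adjusted p = 0.039, but 0.957 with an estimated correlation), led by the co-chaperone Bag3 at −0.25 ± 0.06 (adjusted p = 0.013). So were the genes of amino acid and urea cycle metabolism (24 of 28 lower, median −0.06, adjusted p = 0.043, but 0.957 with an estimated correlation). Of these, Hgd of tyrosine breakdown at −0.18 ± 0.04 and Cdo1 of cysteine breakdown at −0.20 ± 0.06 passed. With centred medians Hgd changed by −0.19 (adjusted p = 0.077), and after quantile normalization Cdo1 changed by −0.19 (adjusted p = 0.052). The female-biased liver genes were higher (9 of 14, median 0.22, adjusted p = 0.046, but 0.957 with an estimated correlation). Among them the V-ATPase subunit Atp6v0d2 was higher by 0.92 ± 0.17, Cyp2a4 by 0.88 ± 0.18 and the transporter Slc22a26 by 1.22 ± 0.36. The steroid hydroxylase Cyp17a1 went the other way at −0.70 ± 0.20. Sex was not among the labels used here. All 4 measured sex chromosome genes had the higher mean in KO-labelled livers (median 0.11, camera adjusted p = 0.21). Of these 0 passed, and 2 did when adjusted over that list alone. Whether the labels differ in sex was not tested. The directional fry test called 0 lists. Adjusted over the list alone, 2 heat shock, 2 amino acid and 6 higher with 1 lower female-biased genes passed.

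Male-biased liver genes went both ways, with 4 higher and 1 lower of 20. Among them the pheromone carrier Mup20 was higher by 0.37 ± 0.07 (adjusted p = 0.00093), Cyp2d9 by 0.64 ± 0.15 (adjusted p = 0.0094), and the complement component C6 was lower, at −0.50 ± 0.12 (adjusted p = 0.011). In lipid handling, Apoa4, an apolipoprotein of triglyceride-rich particles, was higher by 0.56 ± 0.11 (adjusted p = 0.00097, 16 of 18), and Pcyt1a, the regulated enzyme of phosphatidylcholine synthesis, lower, at −0.16 ± 0.05 (adjusted p = 0.035), beside Cd36, so that 1 rose and 2 fell of 25. Baat, which conjugates bile acids, was lower at −0.77 ± 0.10 (adjusted p = 1.5e-05, in all 18). Genes of fatty acid oxidation (26), glycolysis (16), gluconeogenesis (13) and the core clock (17), like the markers of hepatocytes, Kupffer cells, lymphocytes, stellate, endothelial and bile duct cells, held 0 genes past the threshold. Even so, 13 of 14 Kupffer cell markers (median 0.17), 9 of 10 lymphocyte markers (median 0.13) and 20 of 28 acute phase genes, 2 of them past the threshold, had the higher mean in KO-labelled livers. With the acute phase score, Hamp2 included, as covariate Tm7sf2 changed by −0.16 (adjusted p = 0.051), Pcyt1a by −0.12 (0.051) and Slc22a26 by 1.05 (0.054). These no longer passed. In all, 23 of the 35 lists held none. Without 1 array the call ended for 21 arrays in Tm7sf2, 23 in Cdo1, 17 in Slc22a26, 16 in Pcyt1a and 11 in Cyp17a1. The call of Cyp17a1 also ended with a pseudocount of 64, and that of Slc22a26 without the filter. Those of Tm7sf2 and Pcyt1a ended with centred medians and without the filter, and that of Pcyt1a after quantile normalization too.

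At single time points, 63 genes differed between the labels in the SIRT6 cohort at 1 or more times, with 20 at ZT0, 24 at ZT4, 11 at ZT8, 12 at ZT12, 13 at ZT16 and 29 at ZT20, and 56 of the 63 also passed in the daily average. With the lowest 60% of genes left out the 63 became 44, and with array weights 2532. Of the genes called in the main fit, some belong to the clock. The clock repressor Nr1d1 was among the 20 at ZT0, where it read 7.12 ± 0.84 (SD, n = 3) in the KO-labelled and 9.83 ± 0.96 (n = 3) in the WT livers, a log2 fold change of −2.72 (limma adjusted p = 0.0062). At ZT4 it read 10.81 ± 0.34 and 10.66 ± 0.30. Its daily average changed by −0.58 ± 0.18 (adjusted p = 0.057).

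**Figure D2:**
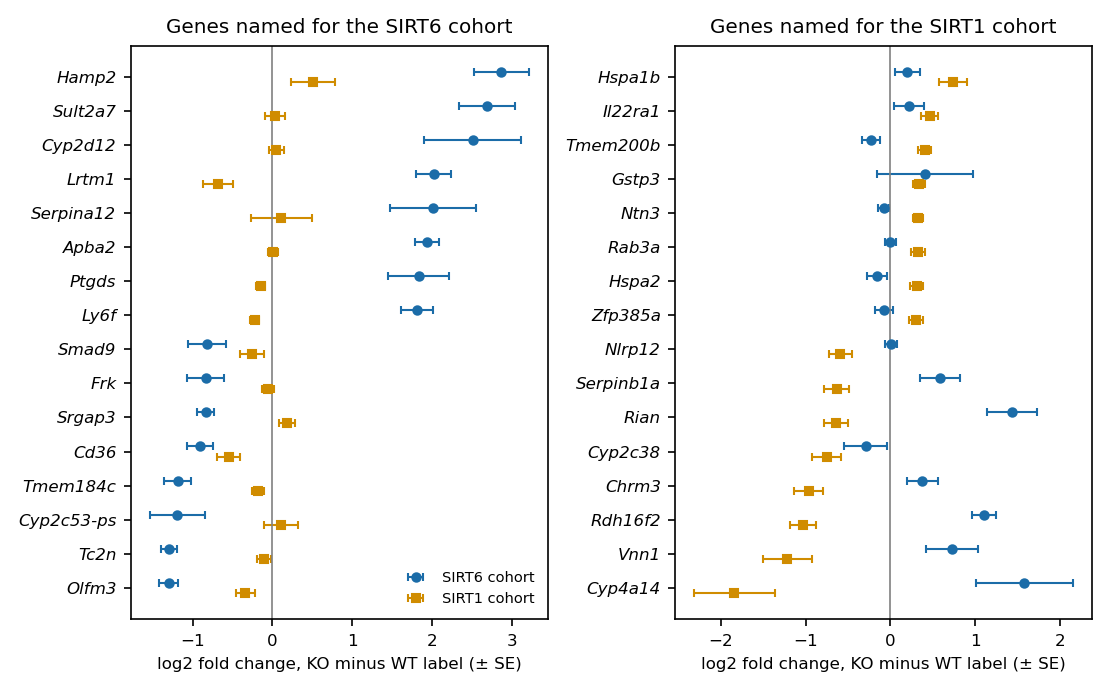
KO minus WT by label, as log2 fold change averaged over 6 time points, with its SE, for the 8 genes with the highest and the 8 with the lowest change past the threshold, among nameable genes with 1 direction at all 6 times, in the SIRT6 cohort (left) and in the SIRT1 cohort (right). Each gene is drawn in both cohorts; the values run from 2.87 for Hamp2 to −1.30 for Olfm3 on the left, and from 0.74 for Hspa1b to −1.84 for Cyp4a14 on the right.

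The daily rhythm of the liver was present in both genotypes of the SIRT6 cohort. With centred medians a 24 h cosine passed in 842 genes of the WT and 1367 of the KO-labelled livers, and with array weights in 3173 and 3549. In the main fit it passed in 1349 genes of the WT and 1415 of the KO-labelled livers, with 584 in both against 143 for independent lists. Of these 584, 87.3% peaked within 2 h of each other in the 2 genotypes, with a median difference of 0.29 h (quartiles −0.65 and 1.08 h). The genes called in 1 genotype alone, 765 in WT and 831 in KO-labelled livers, are not shown to differ, because the test of the difference itself called 13 of 2180, with 388 at an unadjusted p under 0.05. These genes were selected as rhythmic on the same arrays, so their share of small p has no simple chance level, and over all genes the test called 1. The fitted amplitude (peak minus trough) was lower in the troponin gene Tnnc1, at 0.84 ± 0.08 in WT and 0.16 ± 0.09 in KO-labelled livers (adjusted p = 0.0060), and in Srgap3, at 1.66 ± 0.25 and 0.06 ± 0.15 (adjusted p = 0.033). Slc25a48, Cfap77 and Mdga1 were also called for a difference in rhythm, each with another peak time: Slc25a48 peaked at ZT3.2 in WT and ZT20.6 in KO-labelled livers with amplitudes of 0.39 and 0.39. Among the 8 called genes with the higher fitted amplitude in KO-labelled livers, the isoleucyl-tRNA synthetase Iars had 0.25 in WT and 0.53 in KO-labelled livers, the growth regulator Pa2g4 from 0.02 to 0.38, the methyltransferase Spout1 from 0.26 to 0.60, and Coq7 of coenzyme Q synthesis from 0.24 to 0.60, beside Nudt19 and Grm2 (adjusted p = 0.038 for each). These 13 calls fell to 0 after quantile normalization and to 1 without the WT array ZT20 replicate 2, and 8 of 100 relabellings gave as many. The count rose to 401 with array weights and to 42 without the WT array ZT16 replicate 2. After quantile normalization the log2 amplitude ratio was −2.50 for Tnnc1, −4.06 for Srgap3 and 1.37 for Coq7, each at an adjusted p of 0.060. These kept the direction of the amplitudes above, while the ratio of Slc25a48 changed sign. Across 3512 genes rhythmic in the pooled arrays the median log2 amplitude ratio was −0.03 (permutation p = 0.88).

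In the SIRT1 cohort the daily average differed in 302 genes, 141 higher and 161 lower in the KO-labelled livers, with a median size of 0.22, and the larger changes were decreases. The balance of directions turned with the fit, to 187 and 173 after quantile normalization and 830 and 492 with the upper quartile of the arrays as covariate. Asparagine synthetase, Asns, had the largest, at −1.96, without 1 direction at all 6 times. Large decreases were also found in genes that the fatty acid receptor PPARA and the xenobiotic receptor CAR are known to regulate: the fatty acid hydroxylase Cyp4a14 at −1.84 ± 0.47 (adjusted p = 0.036, lower in 16 of 18 KO-labelled arrays), the pantetheinase Vnn1 at −1.21 ± 0.29 (adjusted p = 0.024, 16 of 18) and Cyp2b10 at −1.44 ± 0.27 (adjusted p = 0.0060, 17 of 18). The retinol dehydrogenase family gene Rdh16f2 changed by −1.04 ± 0.15 (adjusted p = 0.0012, 18 of 18), the muscarinic receptor Chrm3 by −0.96 ± 0.17, Cyp2c38 by −0.75 ± 0.17, the imprinted noncoding RNA Rian by −0.64 ± 0.14, the protease inhibitor Serpinb1a by −0.63 ± 0.15 and the NOD-like receptor Nlrp12 by −0.59 ± 0.14. The largest increase of all was in the inducible heat shock gene Hspa1b, at 0.74 ± 0.17 and 1.67-fold (adjusted p = 0.020, higher in 18 of 18). The interleukin 22 receptor Il22ra1 rose by 0.46 ± 0.10, Tmem200b by 0.41 ± 0.08, the glutathione transferase Gstp3 by 0.34 ± 0.08, Ntn3 by 0.33 ± 0.06, the vesicle GTPase Rab3a by 0.32 ± 0.08, Hspa2 by 0.31 ± 0.08 and Zfp385a by 0.30 ± 0.08. Only 2 of the higher and 17 of the lower genes reached 1.5-fold. Without 1 array the call ended for 28 of the 36 arrays in Zfp385a, 14 in Cyp4a14, 7 in Rab3a and 4 in Hspa2. That of Zfp385a also ended with a pseudocount of 1, without the filter, with the replicate block and without the trend. The count of called genes fell to 150 without the WT array ZT0 replicate 3, and 7 other single arrays also moved it below the range of the other 28.

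Of 32 xenobiotic genes 3 were lower and 0 higher, namely Cyp2b10, the main drug hydroxylase Cyp3a11 at −0.18 ± 0.04 (adjusted p = 0.017) and the efflux pump Abcc4 at −0.31 ± 0.07 (adjusted p = 0.027), while the list passed no camera test (adjusted p = 0.49). Of 26 fatty acid oxidation genes, Cyp4a14 and Vnn1 were lower and 0 higher (camera adjusted p = 0.40). Camera at the preset correlation called 2 lists in this cohort. Relabelled arrays gave a median of 6, and 87 of 100 relabellings reached 2, so these calls are not set apart from chance. The heat shock genes were higher on balance in the livers labelled SIRT1 KO (13 of 16 higher, median 0.09, camera adjusted p = 0.019, but 0.942 with an estimated correlation). Hspa1b and the HSP90 co-chaperone Ahsa1, at 0.16 ± 0.03 (adjusted p = 0.015), were past the threshold and 3 adjusted over the list alone. Ribosomal protein genes were lower on balance by a small amount (20 of 22 lower, median −0.05, adjusted p = 0.0037, but 0.942 with an estimated correlation), with 0 past the threshold on their own, for example Rpl10a at −0.14 ± 0.05 (adjusted p = 0.10). The directional fry test called 0 lists. Of the 35 lists, 21 held no gene past the threshold. The clock output factor Hlf, at 0.21 ± 0.05 (adjusted p = 0.028), was the single core clock gene of 17 to pass, and without the WT array ZT0 replicate 3 it changed by 0.19 (adjusted p = 0.056). At single time points limma called 0 genes (smallest adjusted p = 0.092), with 708 to 1622 genes per time point at an unadjusted p under 0.05. The alternative fits called between 0 and 355 genes there.

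Rhythms were called more often in the SIRT1 cohort, in 2440 genes of the WT and 3090 of the KO-labelled livers, with 1545 in both against 567 for independent lists. Of those 1545 genes, 85.1% peaked within 2 h in both genotypes, the KO-labelled livers earlier by a median of 0.49 h (median −0.49 h, quartiles −1.36 and 0.32 h). The test of the difference in rhythm called 0 of 3985 genes (limma, smallest adjusted p = 0.12), with 531 at an unadjusted p under 0.05 among genes selected as rhythmic on the same arrays. It called 24 genes with array weights. The 895 genes called in WT alone and the 1545 called in KO-labelled livers alone are therefore not shown to differ. The median log2 amplitude ratio was 0.02 over 5168 genes (permutation p = 0.87). Where in the day rhythmic genes peaked moved with the scaling of the arrays: between ZT0 and ZT8 lay the peaks of 23.5% of the WT and 46.7% of the KO-labelled genes as deposited, of 28.4% and 36.1% after quantile normalization, and of 34.3% and 31.3% with centred medians. In the SIRT6 cohort these shares were 54.8% and 28.3%, then 35.0% and 32.9%, then 27.7% and 31.7%, so the direction turned in both cohorts.

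The core clock cycled in both genotypes of both cohorts. Of 17 measured clock genes, 14 were rhythmic in WT and 16 in KO-labelled livers of the SIRT6 cohort, and 16 and 16 in the SIRT1 cohort. The activator Arntl peaked at ZT21.2 and ZT21.2 in the SIRT6 cohort, WT first, and at ZT22.0 and ZT21.5 in the SIRT1 cohort, with amplitudes of 3.30 ± 0.35 (SE), 3.45 ± 0.42, 3.83 ± 0.35 and 3.65 ± 0.40 in the same order. The repressor Nr1d1 swung by 4.34 ± 0.35 and 4.61 ± 0.50 in the SIRT6 cohort, with peaks at ZT4.6 and ZT6.2, and by 4.65 ± 0.33 and 4.33 ± 0.21 in the SIRT1 cohort, with peaks at ZT7.0 and ZT6.3. The output factor Dbp swung by 4.12, 4.10, 4.72 and 4.34, and the clock-controlled protease Usp2 by 3.81, 3.41, 4.17 and 3.42. Npas2, a partner of Arntl, and the repressor Ciart completed the 6 genes of largest mean amplitude among the 424 rhythmic in all 4 sets. The smallest adjusted p for a difference in rhythm between the genotypes was 0.23 among clock genes of the SIRT6 cohort, for Nr1d1, and 0.36 in the SIRT1 cohort, for Hlf. Among the clock genes rhythmic in both genotypes, KO minus WT peak times ran from −0.03 to 1.59 h for 13 genes of the SIRT6 cohort and from −1.51 to 0.12 h for 16 of the SIRT1 cohort.

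**Figure D3:**
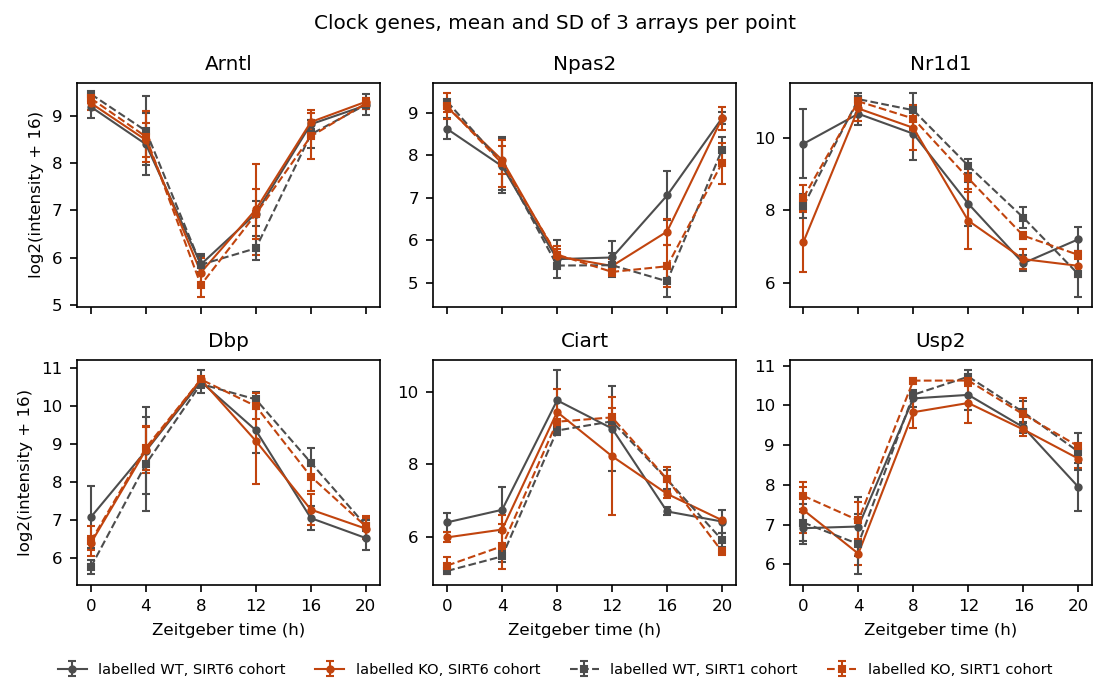
Levels of the 6 genes of largest amplitude over zeitgeber time (h), as log2(intensity + 16), mean and SD of 3 arrays per point, by genotype label (colour) and cohort (line). Each gene cycles in all 4 sets, and Nr1d1 peaks at ZT4.6 and ZT7.0 in the WT and at ZT6.2 and ZT6.3 in the KO-labelled livers of the SIRT6 and SIRT1 cohorts; Nr1d1 at ZT0 reads 9.83 in WT and 7.12 in KO-labelled livers of the SIRT6 cohort.

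The effects of the SIRT6 and SIRT1 labels were not shown to resemble each other across genes. Relabelled arrays gave correlations of the effects with an SD of 0.129, so a weak resemblance is not excluded. The 2 sets of log2 fold changes, which share no arrays, correlated at r = −0.050 (Pearson) and −0.047 (Spearman) across 13308 genes, which are not independent replicates, with a covariance of −0.00076 (permutation p = 0.66 for r). Of the called genes, 11 were higher in both cohorts where independent lists give 4.78, 9 were lower in both against 5.19, and 18 were called in opposite directions against 10. With the SIRT6 labels exchanged, those 18 would share a direction and the others be opposite. Cd36 was lower in both, at −0.91 in the SIRT6 and −0.55 ± 0.14 (adjusted p = 0.039) in the SIRT1 cohort. Rdh16f2 was higher by 1.11 ± 0.14 (adjusted p = 9.1e-06) under the SIRT6 label and lower under the SIRT1 label, at −1.04, and Rian likewise, at 1.44 ± 0.30 (adjusted p = 0.0027) and −0.64. A direct test of the difference between the 2 effects called 767 genes, 338 with the higher effect under the SIRT6 label and 429 with the lower. As labelled, Cyp4a14 had the largest difference, 3.42 ± 0.77 (adjusted p = 0.0038), followed by Lrtm1 at 2.70 ± 0.30, Sult2a7, Cyp2d12, Hamp2 and Cyp2b10. On the other side stood Tc2n at −1.18 ± 0.14, Srgap3, Tmem184c, Olfm3, Baat at −0.78 ± 0.11 and the palmitoyltransferase Zdhhc2 at −0.72 ± 0.18. The effect on rhythm differed in 3 of 4698 genes, Cfap77, Cox10 and Krt33b, of which Cox10 and Krt33b were named after their values were seen. This count was 0 after quantile normalization of the arrays, 45 with the acute phase score as covariate and 1447 with array weights. The order of the differences in the averaged effect rests on the SIRT6 labels: with them exchanged the difference would be 0.25 for Cyp4a14, −1.34 for Lrtm1 and −3.38 for Hamp2. Strain and cohort go with the knockout, so these differences belong to the combination.

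The WT livers of both cohorts shared 713 rhythmic genes, against 247 for independent lists. As deposited, the peaks of these genes lay earlier in the WT of the SIRT6 cohort, by a median difference of −1.35 h (quartiles −2.41 and −0.30 h), and 61.0% lay within 2 h. The gap was not fitted on rescaled arrays, and where rhythmic genes peaked moved with the scaling. Between ZT0 and ZT8 lay 54.8% of the peaks in the SIRT6 WT and 23.5% in the SIRT1 WT as deposited. After quantile normalization these shares were 35.0% and 28.4%, and with centred medians 27.7% and 34.3%. The KO-labelled livers of the same cohorts shared 878 rhythmic genes, with a median difference of −0.47 h. Among core clock genes the medians were −1.64 h for 13 genes in WT and −0.48 h for 16 in KO-labelled livers, while no clock gene passed the test of the difference between the effects on rhythm (smallest adjusted p = 0.14). Mouse strain and cohort go together here.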

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

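The tests of exchanged labels, of the chromosome segment, of array brightness, of array scaling and of the inflammatory state, and all counts over relabelled arrays, were chosen only after the result was seen.

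The Sirt6 probe set was higher in the arrays labelled SIRT6 KO, by 0.57 on the log2 scale. An exchange of single arrays is excluded, since 0 KO-labelled arrays lay at or below the highest WT-labelled array. An exchange of the labels of the whole cohort cannot be told from the data: the KO-labelled arrays lay 0.44 above the 36 arrays of the SIRT1 cohort and the WT-labelled arrays −0.13 from them, where the central range across genes was −0.59 to 0.87 for the former. The position of the probes relative to the deleted exons is not known, so the labels are used as given.

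Single genes differed strongly between the labels in the SIRT6 cohort. Calls were not more frequent near Sirt6, where 4% of the 100 nearest tested genes were called against 6.62% elsewhere. A window of 100 genes could not hold the bulk of the 880 called genes in any case. Whether single called genes lie in a chromosome segment carried along with Sirt6 stays open. Array brightness was examined with the upper quartile of each array as covariate, which gave 1668 called genes, 705 higher and 963 lower. The upper quartile followed the main component of the variation within groups (r = 0.92). As a covariate it also takes out that variation, so a higher count does not decide the question. After quantile normalization 931 genes were called, 476 higher and 455 lower, so the count itself was kept without differences in brightness. A genetic background differing between WT and KO mice, planned as a test, cannot be told: the correlation with the difference to C57BL/6 was −0.073 as the median of 50 halvings of the WT arrays, with a range from −0.342 to 0.142, and neighbouring genes were both called 78 times against a mean of 57.4 and a highest of 79 over shuffled orders.

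Livers of 1 group varied more in the SIRT6 than in the SIRT1 cohort, with a median residual SD of 0.222 against 0.151, and 52.6% against 18% of this variance on 1 component. Array scaling is excluded, because the share was 51.0% after quantile normalization, although this component followed the upper quartile of the arrays at r = 0.92. A lower share of hepatocytes in some samples, planned as a test, cannot be told. The slopes of the cell type lists on the acute phase score differed by 1.47 between lymphocyte and endothelial markers (1.49 against 0.019). This argues against an equal rise of all other cell types. A lower share through more lymphocytes or macrophages would also give unequal slopes, so the test cannot decide it. Hepatocyte markers fell with the score (r = −0.790, median slope −0.107). Stellate (r = 0.651) and bile duct markers (r = 0.605) rose, while endothelial markers (r = 0.356, slope near 0) are not shown to. An inflammatory state of single livers may underlie the variation, and the interferon score followed the acute phase score at r = 0.885 within groups. This correlation cannot single out inflammation. Of 13280 genes 2603 rose and 4298 fell with the score, and the p53 list followed it too (r = 0.710). The quality of the RNA is not given and stays open.

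Genotypes were exchanged within time points, or times within a set, 100 times with the real data counted in. For the counts given first, at most 3 of 100 reached the real one. This makes chance less likely but does not exclude it, as these tests were not adjusted for their number. Averaged over time in the SIRT6 cohort, 3 of 100 reached the real 880 (highest other 2563). At any time point there it was 1 (63, other 3), for rhythms in its WT 2 (1349, other 2507) and in its KO-labelled arrays 1 (1415, other 0). In the SIRT1 cohort it was 1 for the average (302, other 1), 1 for rhythms in WT (2440, other 8) and 1 in KO-labelled arrays (3090, other 3). For the difference between the effects it was 3 (767, other 1508), and for rhythms shared by the WT sets 1 (713, other 0). More splits reached the real count for the difference in rhythm in the SIRT6 cohort, 8 (13, other 2733), and for the difference between effects on rhythm, 7 (3, other 1843). The same holds for the amplitude ratios, 88 (−0.03, other 0.35) and 87 (0.02, other 0.22), the gene lists, 79 (4, other 19) and 87 (2, other 12), and the correlation of the effects, 66 (−0.050, other −0.297). Chance stays open for all of these. The other splits called a median of 7 lists in the SIRT6 and 6 in the SIRT1 cohort. In the SIRT1 cohort the real counts of differences in rhythm and of genes at single time points were 0, which each of the 100 splits reaches by design (highest other 287 and 5), so these splits say nothing about chance. Splits that called several times the real count point to a structure of the samples, whose source was not tested.

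Differences between the effects of the SIRT6 and SIRT1 labels (log2) were 3.42 for Cyp4a14, 2.70 for Lrtm1, 2.66 for Sult2a7, 2.46 for Cyp2d12, 2.36 for Hamp2 and 2.33 for Cyp2b10. They were −1.18 for Tc2n, −1.02 for Srgap3, −1.01 for Tmem184c, −0.96 for Olfm3, −0.78 for Baat and −0.72 for Zdhhc2. These rest on the SIRT6 labels; with them exchanged the values would be, in the same order, 0.25, −1.34, −2.73, −2.56, −3.38, 0.56, 1.40, 0.65, 1.37, 1.64, 0.76 and 0.26 (Cyp4a14 to Zdhhc2). In all, 767 genes differed in the averaged effect and 3 in the effect on rhythm. Of 7372 probe sets without a gene symbol above the filter, 138 were called in the SIRT6 cohort (84 higher, 54 lower) and 267 in the SIRT1 cohort (72 higher, 195 lower).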

How the results depend on the processing

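The covariates and the fit without the array WT ZT12 replicate 1 of the SIRT6 cohort were chosen only after the result was seen. The cause of the moves below was not tested. Counts are of genes; SIRT6 and SIRT1 name the cohorts, rhythm difference is that between KO and WT, and effect difference that between the cohorts.

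Quantile normalization gave 0 rhythm differences and 1 list in SIRT6, 1 list in SIRT1 and 0 effect differences in rhythm. Centred medians gave 842 rhythmic in SIRT6 WT, 0 rhythm differences and 0 effect differences in rhythm. No filter gave 28 (SIRT6) and 1 (SIRT1) rhythm differences and 6 lists in SIRT1. With the lowest 60% out there were 0 rhythm differences and 1 list in SIRT6, 0 effect differences in rhythm, and 159 higher and 111 lower genes in SIRT1. With a block for the replicate number, 849 and 288 genes were called on average, 1 at any time in SIRT1 and 1 effect difference in rhythm. The numbers were not used to pair samples, and whether they pair WT and KO arrays of the same time stays open. Between such arrays r had a mean of 0.222 and ran from −0.361 to 0.743 in SIRT6, with 10 of 18 WT arrays best matched to their own number. In SIRT1 the mean was 0.017, the range −0.284 to 0.370, and 6 of 18 matched. Over all times same-number arrays correlated at 0.0097 and others at −0.0059 in SIRT6, and at −0.0033 and 0.0016 in SIRT1. These last values and the block join equal numbers over all times, so they do not test pairs within a time point.

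Array weights gave in SIRT6 2623 averaged, 2532 at any time, 3173 and 3549 rhythmic in WT and KO and 401 rhythm differences; in SIRT1 1044 averaged (575 higher, 469 lower), 355 at any time, 24 rhythm differences and 1 list; and 2439 effect differences, 1447 in rhythm, and 1483 rhythmic in both WT. The upper quartile as covariate gave 1668 averaged (705 higher, 963 lower), 195 at any time, 2266 rhythmic in KO and 21 rhythm differences in SIRT6, 1322 averaged in SIRT1 (830 higher, 492 lower), 1786 effect differences, 8 in rhythm, and 1107 shared by the WT. The acute phase score as covariate gave 1709 averaged (689 higher, 1020 lower; 451 and 429 without it), 225 at any time, 49 rhythm differences and an amplitude ratio of 0.11 in SIRT6, and 1184 effect differences, 45 in rhythm. Without the doubted array SIRT6 gave 1030 averaged, 69 at any time, 1099 rhythmic in WT, 11 rhythm differences, a ratio of 0.02 and 5 lists.

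All probe sets gave 628 in SIRT1 (218 higher, 410 lower), 66 at any time, 11 rhythm differences and 15 effect differences in rhythm. A single fit of 72 arrays gave 153 (SIRT6) and 1 (SIRT1) at any time; for the effect difference it is the main design itself. A threshold of 0.01 gave 395 and 43. Estimated correlation and directional fry gave 0 lists in either cohort, and fry for changes in both directions 7 in SIRT6 and 1 in SIRT1. Any difference among the 6 times was called in 410 (SIRT6 WT), 480 (SIRT6 KO) and 1266 (SIRT1 WT), and by the rank test 879, 924 and 1503. Rhythm differences in SIRT6 were 1 over all genes and 1 with 5 terms per genotype. Without the trend 20 effect differences in rhythm were called.

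Leaving out each array in turn gave in SIRT6 737–1030 averaged, 0.55–0.60 for Sirt6, 45–74 at any time, 901–1585 and 1034–1580 rhythmic in WT and KO, 1–42 rhythm differences (21 of 36 arrays moved it), ratios of −0.07 to 0.03 and 0–5 lists. In SIRT1 it gave 150–436 averaged, −0.01 to 0.02 for Sirt1, 0–6 at any time, 1992–2642 and 2583–3544 rhythmic, 0–0 rhythm differences, ratios of −0.03 to 0.06 and 1–3 lists. Between cohorts it gave 632–930 effect differences, 0–74 in rhythm (26 of 72 arrays), r of −0.066 to −0.031 and 538–718 rhythmic in both WT. Reversed were the log2 amplitude ratios of Slc25a48 (0.24 quantile, 0.20 medians, 0.56 weights, 0.0011 without the doubted array, −0.23 to 0.12 without 1 array, above 0 for 16 arrays), Grm2 (−0.10 medians) and Cfap77 (0.51 weights). Cdo1 also lost its call in SIRT6 with no filter (−0.20), the block (−0.20) and without the doubted array (−0.20). Of 38 named calls in SIRT6, 11 were lost without an array and 8 in a setting; of 25 in SIRT1, 6 and 2.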

Other observations

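All tests in this part except that of a background difference, which was planned, were chosen only after the result was seen. Livers of the same group in the SIRT6 cohort differed in an inflammatory and interferon program, and core clock genes were lower on balance where it was high. This was part of a broad variation: of 13280 genes, 2603 were higher and 4298 lower with the acute phase score, and the first component of the variation within groups followed the upper quartile of the arrays at r = 0.92. With the group means taken out, a higher mean of the acute phase genes went with higher interferon genes (r = 0.885, Spearman 0.918, 36 arrays, permutation adjusted p = 1.7e-05, r = 0.924 without the 2 farthest arrays), Kupffer cell markers (r = 0.819) and lymphocyte markers (r = 0.798), and with lower fatty acid oxidation genes (r = −0.866) and core clock genes (r = −0.758). Stellate (r = 0.651) and bile duct markers (r = 0.605) were also higher and hepatocyte markers lower (r = −0.790, median slope −0.107). Endothelial markers (r = 0.356, permutation adjusted p = 0.036) are not shown to rise, because the permutation ignores the removed group means and gives too small a p. Of 17 clock genes 9 were lower with the score and 1 higher, while Clock, Npas2, Per1, Cry1, Rora, Nfil3 and Bhlhe40 did not pass. Per unit of the score Hlf changed by −0.57 ± 0.07 (SE, limma adjusted p = 6.0e-07), Tef by −0.74 ± 0.14, Bhlhe41 by −0.98 ± 0.21, Ciart by −1.12 ± 0.26, Cry2 by −0.42 ± 0.09, Dbp by −0.79 ± 0.25, Per3 by −0.49 ± 0.15, Nr1d1 by −0.66 ± 0.25 and Nr1d2 by −0.40 ± 0.16, whereas Arntl changed by 0.38 ± 0.15 (adjusted p = 0.035). In the SIRT1 cohort the score varied less (SD 0.177 against 0.349) and went with the interferon genes at r = 0.640 (0.486 without the 2 farthest arrays), but not with the clock genes (r = −0.221). A systemic immune stimulus in some mice may produce this: serum amyloid and interferon measured in the same animals would be raised in those with low Hlf and Tef, and housing or infection records would sort them.

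Peak times of the cohorts were compared in the values as deposited, and not after rescaling of the arrays. The clock genes of the WT livers peaked earlier in the SIRT6 than in the SIRT1 cohort. All 13 clock genes rhythmic in both WT sets peaked earlier there, by a median difference of −1.64 h (range −2.64 to −0.67 h), with 5 past a test of the difference, and of 713 shared rhythmic genes 68 passed, 66 of them earlier. In the KO-labelled sets of the same cohorts the median over 16 clock genes was −0.48 h (range −0.96 to 0.74 h), with 12 earlier and 0 past the test, and of 878 shared genes 49 passed, 29 of them earlier. The gaps of the 2 genotypes were not shown to differ, strain and cohort go together, and the source of the gap was not tested. Among the genes with large changes, Cyp2d12 ran from 5.0 to 11.38 in the WT of the SIRT6 cohort, with a gap of 3.13 above 12 arrays, from 9.05 to 11.50 in its KO-labelled arrays and from 4.55 to 5.95 in the SIRT1 cohort. Gstp3, which was called in the SIRT1 cohort alone, ran from 8.31 to 12.67 in the WT of the SIRT6 cohort, with a gap of 2.84. In the KO-labelled arrays of that cohort it ran from 7.83 to 12.37, with a gap of 3.02. Alleles segregating on the mixed background may underlie such levels; the test of a background difference gave −0.073 and could not tell, and genotyping at Cyp2d12 would.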
